A study of Homo sapiens with 6 samples.

How the data were processed

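CAOV2 cells were transfected with 100 pmol of siRNA and 6 µL of lipid reagent for 2 days and collected at day 3, per the labels' protocols. The siRNA reagent against YAP and the non-targeting control came from different suppliers, per the labels' protocols, so that reagent and group cannot be separated. Libraries were made with a stranded poly(A) kit, per the labels' protocols. There were 3 siNT and 3 siYAP libraries, grouped by their titles.

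The deposited table holds one signal value per gene and library. Per the submitters' processing notes, FastQC, HISAT2, HTSeq and DESeq2 were used, with the builds hg19 and mm9. The versions, the role of each build, the annotation release, the strand setting of the counting and the filter that chose the listed genes are not given in the sources used here. The values of the deposited signal are normalized read counts: in each library, 100% of the values were whole multiples of the smallest positive value within 0.01 of a read, with a largest departure of 0.000186. The recovered reads summed to between 25478595 (siNT replicate 3) and 31790340 (siYAP replicate 1), and the normalized counts to between 30291799 and 30788706 in siNT and between 28652879 and 28808397 in siYAP. One read was worth between 0.906 and 1.21 normalized counts, which sets the smallest step at the floor.

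The test planned for raw counts, edgeR, was replaced by the one planned for a normalized unit. Values were analysed as log2(value + 1) with limma 3.58.1 (trend and robust empirical Bayes) in R 4.3.3, for genes with a value of at least 1 in 3 or more libraries: 17200 of 17211 listed genes. The design had group alone. P-values were adjusted by Benjamini-Hochberg and called under 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low genes, and SDs are over normalized counts. As alternatives chosen after seeing the data, the recovered reads were tested with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr), which called 4916 genes higher and 4655 lower of 15659 tested, and with DESeq2 1.42.0, which called 4393 higher and 4385 lower. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1 and was not used.

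A total of 24 gene lists were fixed before the data were examined, on YAP and Hippo signalling, ferroptosis, the cell cycle, stress, immunity, matrix, cytoskeleton, metabolism and cell types; 471 of their 542 symbols were measured. They were tested with camera (preset inter-gene correlation of 0.01, variance trend), with the correlation also estimated per list, and with fry. Genes were named by a rule fixed at the same time. It took YAP1 and the other preset genes, and the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 and no overlap between groups. From each list it took up to 4 members by smallest p where the list passed and up to 2 otherwise. Of 74 genes so named, 73 were measured, of which 1 is not reported here, and 25 of the 73 overlap another listed gene in the annotation.

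Gene symbols came from a table of human names by Ensembl identifier (16662 of 17211 matched, 16743 with the symbols of GENCODE 29). Coordinates and 3′ UTR sequences are those of GENCODE 29 on GRCh38, matched by identifier, since the deposited values carry none. A single annotated transcript per gene was used, a principal isoform where given and then the longest 3′ UTR, so that other isoforms were not searched. Its 3′ UTR, of at least 20 bases, was searched for all heptamers present in at least 50 genes (16158 heptamers, 11396 genes with a mean of at least 50). The log2 fold change, limited to ±2, was regressed on the presence of each with UTR length, base content and expression, against a Bonferroni limit of 4.66 on the statistic. Heptamers sharing 5 or more bases in a row were merged.

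The alternatives were other scalings, filters, pseudocount 0.1, limma without trend, the replicate number as a block, each library left out, equal totals and genes without the heptamers. In simulated counts with 200 changed genes, limma recovered 30 of 50 changed 1.2-fold, 43 of 50 changed 1.5-fold, 50 of 50 changed 2-fold and 49 of 50 changed 3-fold, with 6 false calls over the 17194 simulated genes that were tested. The changed genes all had a mean of at least 20 normalized counts, and the spread followed a trend over expression. The recovery thus does not cover genes near the floor, nor data with as many changed genes as were called here. Camera found the 1 shifted list of 20 simulated lists and called 0 of the other 19. The simulated genes were drawn independently, so this does not test camera on lists whose members are correlated. The heptamer regression returned -0.141 for a planted effect of -0.15 over 11396 genes. Within groups, libraries correlated at 0.992 to 0.994 (Pearson, log2 values) and differed by more than sampling noise (chi-square per degree of freedom 2.75 to 7.5), so none was counted as a duplicate. The first principal component held 69.5% of the variance.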

Results

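Poly(A) RNA-seq was done on CAOV2, a human ovarian cancer cell line, after transfection with an siRNA reagent against YAP (siYAP, 3 libraries) or with a non-targeting siRNA (siNT, 3 libraries). The labels name it as a cell line, while the sample titles also call the cells primary. YAP, encoded by YAP1, is a transcriptional co-activator that is held in check by the Hippo kinase pathway and acts through TEAD transcription factors. The values are read counts per gene divided by one size factor per library, and the whole reads behind them came to between 25478595 and 31790340 per library over the 17211 listed genes. The labels call the libraries biological replicates but do not say whether they came from separate passages or days, so the p-values measure the spread between these libraries. The only contrast in the design asks which transcripts differ between cells given the siRNA reagent against YAP and cells given the control. These reagents came from different suppliers, so loss of YAP and other effects of either reagent cannot be told apart.

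YAP1 itself (ENSG00000137693, protein-coding, GRCh38 chromosome 11, 102110461 to 102233423, plus strand) fell to 5.00% of its control level. Its normalized read counts were 6221, 5801 and 5955 in the siNT libraries and 278, 327 and 294 in the siYAP libraries. The means were 5992 ± 213 (SD, n = 3) and 299.6 ± 24.7 (SD, n = 3), a log2 fold change of -4.32 with a standard error of 0.0593 (limma, adjusted p = 1.00e-22). It was the gene with the largest fall among those that passed the rule for named genes, and no siYAP library overlapped an siNT library.

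WWTR1, which encodes the YAP paralog TAZ, also fell, from 4278 ± 73.2 to 2414 ± 59.3 normalized counts (SD, n = 3; log2 -0.83). SKP2, the substrate-recognition subunit of an SCF ubiquitin ligase, fell by 0.73 on the log2 scale, and EMP1, an epithelial membrane protein, fell by 0.77. ANGPTL4, a secreted inhibitor of lipoprotein lipase, fell from 1516 ± 82.9 to 672.9 ± 3.54 normalized counts (SD, n = 3; log2 -1.17). Among the standard YAP readouts, CCN1 fell slightly (log2 -0.27, standard error 0.0459), while CCN2 and ANKRD1 rose, both by 0.48 on the log2 scale with standard errors of 0.0435 and 0.0475. The limma adjusted p-values of these 7 genes lay between 1.30e-13 and 2.52e-05. CYBB, a subunit of the phagocyte NADPH oxidase, was near the floor, at 5.48 ± 1.63 and 6.47 ± 5.71 normalized counts (SD, n = 3; limma adjusted p = 0.929), and NOX4 was not analysed here. The 3′ UTRs of WWTR1, SKP2 and EMP1 hold at least 1 of 3 heptamers described further on, whereas those of CCN1, CCN2 and ANGPTL4 hold none of them. That of ANKRD1, which rose, holds 1.

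**Figure D1:**
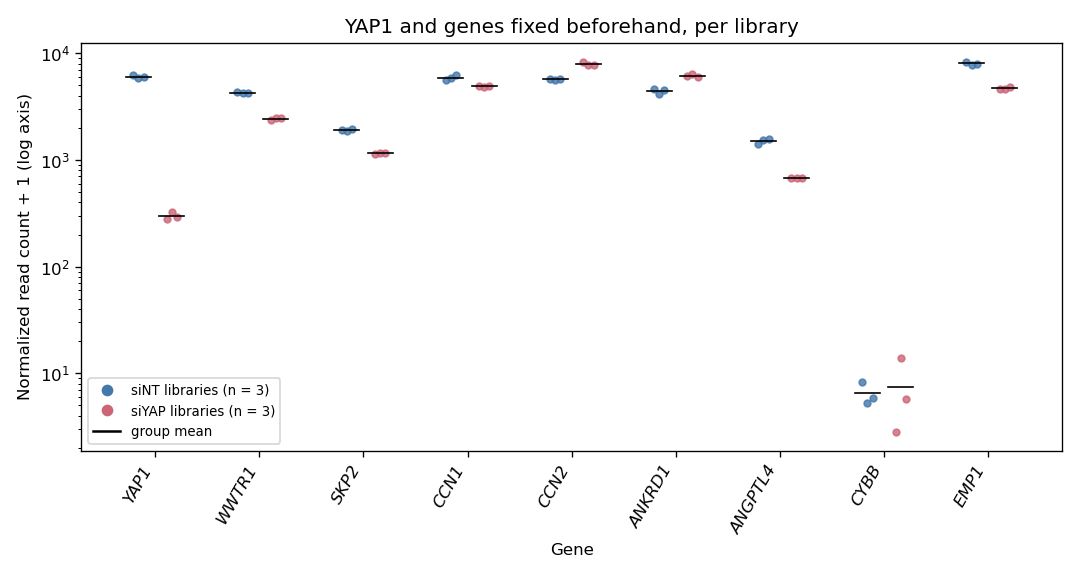
Normalized read counts plus 1 (log axis) of YAP1 and 8 genes fixed beforehand, with one point per library and a bar at each group mean (3 siNT and 3 siYAP libraries). The siYAP libraries lie between 278 and 327 normalized counts for YAP1 against 5801 to 6221 in siNT, and above the siNT libraries for CCN2 and ANKRD1.

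Over the whole transcriptome, 4926 genes were higher and 4841 lower in siYAP, 9767 of the 17200 tested (56.8%) at an adjusted p under 0.05. Most of these changes were small. The median absolute log2 fold change of the called genes was 0.43, and 2157 of them (22.1%) moved by under 0.25 on the log2 scale. At least 2-fold changes were seen in 1086 genes that rose and 439 that fell. In 10586 genes (61.5%) the 3 libraries of one group lay all above or all below those of the other, against 10% by chance. When the libraries were rescaled to equal totals over the listed genes, 62.1% of the called genes were higher in siYAP (6050 higher and 3700 lower), against 50.4% with the authors' size factors.

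The largest rises were in genes with little or no signal in the control. COL4A4, a basement membrane collagen chain, went from 0, 1.05 and 1.07 to 79.6 ± 6.10 normalized counts (SD, n = 3; log2 5.64 on the log2(value + 1) scale, which understates the change of low genes). The sodium-glucose transporter gene SLC5A9 (log2 5.34), GAS2 (log2 5.24), and the cytochrome P450 genes CYP4F12 (log2 5.14) and CYP4F3 (log2 4.84) followed the same course. With a pseudocount of 0.1 the log2 fold change was 7.28 for COL4A4 and 7.59 for GAS2, so the size of such rises depends on the pseudocount. AGT, the precursor of angiotensin, rose from 10.6 ± 6.60 to 413 ± 18.0 normalized counts, and VTN, the plasma adhesion protein vitronectin, from 65.0 ± 9.31 to 1839 ± 44.4 (SD, n = 3). PLXNC1, a semaphorin receptor, rose from 18.6 ± 14.6 to 514 ± 14.8 (SD, n = 3), with limma adjusted p = 0.00148. Its siNT mean rests on replicate 2 (8.38, 35.3 and 12.1 normalized counts in replicates 1, 2 and 3), as does that of AGT (6.28, 18.2 and 7.25). CYP4F12 and CYP4F3 are close paralogs that may share reads. GAS2, PLXNC1 and VTN overlap listed genes on the other strand (FANCF, CEP83 and SARM1), whose reads cannot be told apart from theirs unless strand was used in counting, and SARM1 itself differed by a log2 of 1.44.

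After YAP1, the largest falls were in PRSS33, a serine protease gene (log2 -3.98), and HES2, a Hairy and Enhancer of split family repressor (log2 -3.80). GMFG (log2 -3.31), VSIG1 (log2 -3.29) and LCK, a SRC-family tyrosine kinase best known from T cells (log2 -3.20), came next. TNS4, a focal adhesion adaptor, fell by 3.00 on the log2 scale. MMP1, an interstitial collagenase, fell from 925 ± 125 to 117 ± 17.6 normalized counts (SD, n = 3; log2 -2.97, limma adjusted p = 9.60e-16). Of these 7, the 3′ UTR of HES2 holds 2 of the 3 heptamers and the other 3′ UTRs none. Single libraries near the floor moved 2 of the values: PRSS33 was at -3.32 without siYAP replicate 1 and HES2 at -4.39 without siYAP replicate 2. With a pseudocount of 0.1, PRSS33 was at -5.30.

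**Figure D2:**
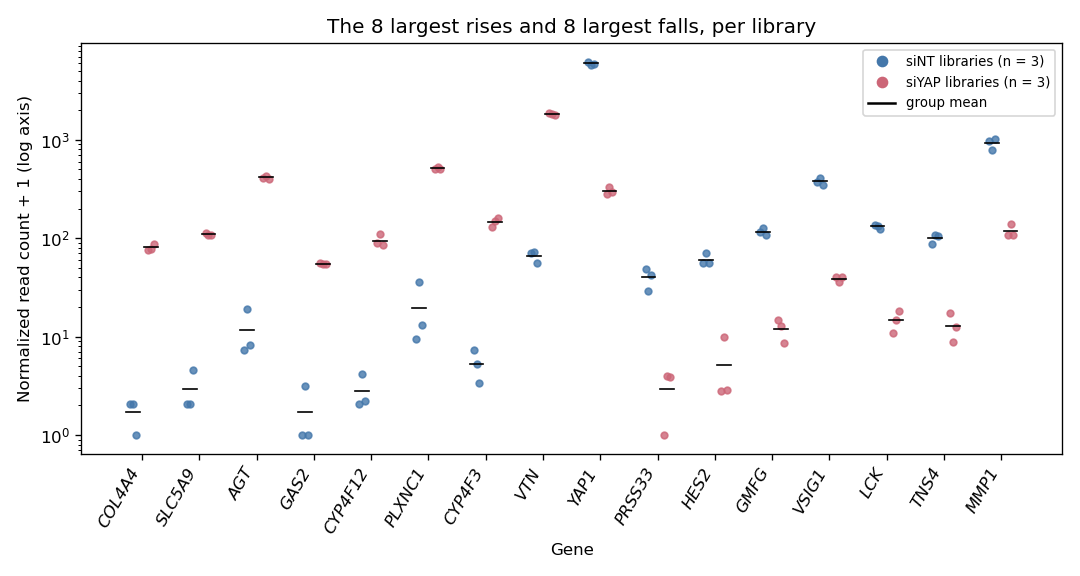
Normalized read counts plus 1 (log axis) of the 8 genes with the largest rises and the 8 with the largest falls, with one point per library and a bar at each group mean (3 siNT and 3 siYAP libraries). For each gene the groups do not overlap, a condition of the rule that chose them, and VTN moves from a mean of 65.0 to 1839.

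Genes of DNA replication fell together. Of the 37 measured members of this list, 33 were lower, 1 was higher and 3 were not called, and adjusted over the list alone 33 were lower and 2 higher. RRM2, a ribonucleotide reductase subunit, fell most among the 4 named members, from 13048 ± 542 to 5210 ± 142 normalized counts (SD, n = 3; log2 -1.32). The replicative helicase subunits MCM2 (log2 -0.95) and MCM7 (log2 -0.88) and the transcription factor E2F1 (log2 -0.88) also fell. The list had a median log2 fold change of -0.49 and a camera adjusted p of 2.65e-13, and adjusted p = 0.0681 with an estimated correlation, so that the call was lost. The 3′ UTR of RRM2 holds 2 of the 3 heptamers, and those of MCM2, MCM7 and E2F1 hold none.

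Genes of mitosis were also lower: 29 of 34 members fell, 1 rose and 4 were not called, with 30 lower and 1 higher adjusted over the list alone. KIF2C, a microtubule-depolymerising kinesin, fell to 50.1% of its control level. The spindle assembly factor TPX2 (log2 -0.67), the E2 enzyme of the anaphase-promoting complex UBE2C (log2 -0.69) and the checkpoint kinase BUB1 (log2 -0.56) fell less. The list's median was -0.29 and its camera adjusted p 8.82e-09, with adjusted p = 0.636 with an estimated correlation.

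Among genes of the actin cytoskeleton, 17 of 30 members fell, 4 rose and 9 were not called, with the same counts adjusted over the list alone. Gamma-actin, ACTG1, fell from 101270 ± 4203 to 49875 ± 1942 normalized counts (SD, n = 3; log2 -1.02), and the cross-linker filamin A, FLNA, by 0.68 on the log2 scale. MYLK, myosin light chain kinase, fell (log2 -1.24), and CALD1, caldesmon, rose (log2 0.99). The camera test gave an adjusted p of 0.00565 and a median of -0.29, and adjusted p = 0.665 with an estimated correlation. Among the 23 members whose searched 3′ UTR holds none of the 3 heptamers, 11 were lower and 4 higher, the median was -0.07 and the camera test no longer passed (adjusted p = 0.142).

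In the list of hypoxia and glycolysis genes, 15 of 25 members fell, 6 rose and 4 were not called, with the same counts adjusted over the list alone. The pyruvate kinase gene PKM fell from 154930 ± 4440 to 84392 ± 2067 normalized counts (SD, n = 3; log2 -0.88), and the lactate dehydrogenase gene LDHA (log2 -0.57), the glucose transporter gene SLC2A1 (log2 -0.67) and the stress-responsive NDRG1 (log2 -1.24) fell too. The camera adjusted p was 0.0264 and the median -0.19, with adjusted p = 0.665 with an estimated correlation. The call was lost without siNT replicate 2 (adjusted p = 0.0529) and among the 19 members without the 3 heptamers (adjusted p = 0.142), whose median was again -0.19, with 11 lower and 5 higher.

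The YAP/TAZ target signature went both ways. Of 21 measured members, 10 rose, 7 fell and 4 were not called, with the same counts adjusted over the list alone, and the camera test did not pass (adjusted p = 0.795). AMOTL2, a scaffold that binds YAP (log2 -0.89), and TGFB2, a TGF-beta ligand (log2 -0.68), fell, beside the rise of CCN2 and ANKRD1. The 3′ UTRs of AMOTL2 and TGFB2 each hold 1 of the 3 heptamers. Among Hippo pathway components, 8 of 28 rose, 10 fell and 10 were not called (also adjusted over the list alone; camera adjusted p = 0.761). TEAD2, one of the DNA-binding partners of YAP, fell from 1775 ± 82.7 to 620.5 ± 71.9 normalized counts (SD, n = 3; log2 -1.52), and its 3′ UTR holds 1 of the heptamers.

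Ferroptosis is an iron-dependent cell death driven by lipid peroxidation. Among genes that promote it, 7 of 16 measured members fell, 3 rose and 6 were not called, also adjusted over the list alone (camera adjusted p = 0.165), and ANGPTL4 and EMP1, described above, had the smallest p-values. Among genes that suppress it, 9 of 25 rose, 10 fell and 6 were not called, also adjusted over the list alone (camera adjusted p = 0.795). SLC7A11, the cystine importer of system xc-, rose from 369.7 ± 53.3 to 1436 ± 140 normalized counts, and SLC40A1, the iron exporter ferroportin, from 53.8 ± 8.50 to 351 ± 28.8 (SD, n = 3). Genes of SCF ubiquitin ligases did not pass as a list (5 of 16 lower, 4 higher and 7 not called, also adjusted over the list alone; camera adjusted p = 0.568), with SKP2 and the F-box gene CCNF (log2 -0.58) lower.

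Several lists on growth signalling held large single changes without passing as lists. Of 8 measured ERBB ligands and receptors, 4 rose, 3 fell and 1 was not called (also adjusted over the list alone; camera adjusted p = 0.390). ERBB3 rose from 1850 ± 102 to 6468 ± 171 normalized counts (SD, n = 3; log2 1.81), and ERBB2 from 1077 ± 35.0 to 2484 ± 93.3 (SD, n = 3). Among immediate early genes, 11 of 20 fell, 5 rose and 4 were not called (12 lower and 5 higher adjusted over the list alone; camera adjusted p = 0.0976). DUSP6, a phosphatase that removes ERK activity, fell by 1.64 on the log2 scale and IER3, an early response gene, also fell (log2 -1.17), and the 3′ UTR of DUSP6 holds 1 of the heptamers. Genes of cholesterol synthesis rose in 11 of 22 cases, fell in 5 and were not called in 6 (11 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.149), with HMGCS1, the cytosolic HMG-CoA synthase gene, higher (log2 1.02).

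Stress and immune lists did not pass either. Among p53 targets, 9 of 24 rose, 9 fell and 6 were not called (also adjusted over the list alone; camera adjusted p = 0.795), with BTG2 (log2 1.49) and TP53I3 (log2 0.59) higher. Among ATF4 and unfolded protein response genes, 10 of 23 rose, 6 fell and 7 were not called (10 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.149), with SLC7A11 and the transcription factor gene XBP1 (log2 0.63) higher. Interferon-stimulated genes were higher in 11 of 30 cases, lower in 1 and not called in 18 (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.127). IFI35 (log2 0.72) and RIGI, a sensor of viral RNA (log2 0.52), were among those that rose. Of 17 inflammatory cytokine genes, 7 rose, 6 fell and 4 were not called (also adjusted over the list alone; camera adjusted p = 0.795), and PTGS2, the inducible cyclooxygenase (log2 -1.54), and CSF2, encoding GM-CSF (log2 -1.71), fell.

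In the matrix and adhesion lists, 18 of 29 extracellular matrix genes fell, 8 rose and 3 were not called (18 lower and 9 higher adjusted over the list alone; camera adjusted p = 0.0976). TGFBI, a secreted matrix protein gene, fell (log2 -0.93) and COL3A1, a fibrillar collagen gene, rose from 661 ± 76.9 to 3060 ± 79.0 normalized counts (SD, n = 3; log2 2.22). Of 27 integrin and focal adhesion genes, 14 fell, 6 rose and 7 were not called (also adjusted over the list alone; camera adjusted p = 0.262), with paxillin, PXN, lower (log2 -0.93) and the collagen-binding integrin gene ITGA1 higher (log2 1.53). ITGA1 overlaps the listed gene PELO on the same strand.

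Markers of cell identity moved singly. Among epithelial markers, 7 of 18 rose, 5 fell and 6 were not called (also adjusted over the list alone; camera adjusted p = 0.993), with keratin 7, KRT7, lower (log2 -0.97) and the tight junction gene CLDN7 higher (log2 1.09). Among mesenchymal markers, 3 of 12 rose, 3 fell and 6 were not called (also adjusted over the list alone; camera adjusted p = 0.664), with vimentin, VIM (log2 -0.89), and S100A4 (log2 -0.50) lower. Of 6 measured ovarian carcinoma markers, CRABP2 rose (log2 0.90), MECOM fell (log2 -0.94) and 4 were not called, also adjusted over the list alone (camera adjusted p = 0.993). Among markers of other cell types, 3 of 5 measured immune markers fell, 1 rose and 1 was not called (also adjusted over the list alone; camera adjusted p = 0.568), with CD79A at 64.6 ± 6.99 against 24.0 ± 4.81 normalized counts and LYZ at 20.9 ± 1.92 against 6.35 ± 1.35 (SD, n = 3). Of 6 fibroblast markers, 4 rose, 1 fell and 1 was not called (also adjusted over the list alone; camera adjusted p = 0.0976), with COL3A1 and the proteoglycan gene LUM (log2 1.37) higher. The 1 measured endothelial marker, ESAM, fell (log2 -0.45), alone in its list and untested as a set.

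**Figure D3:**
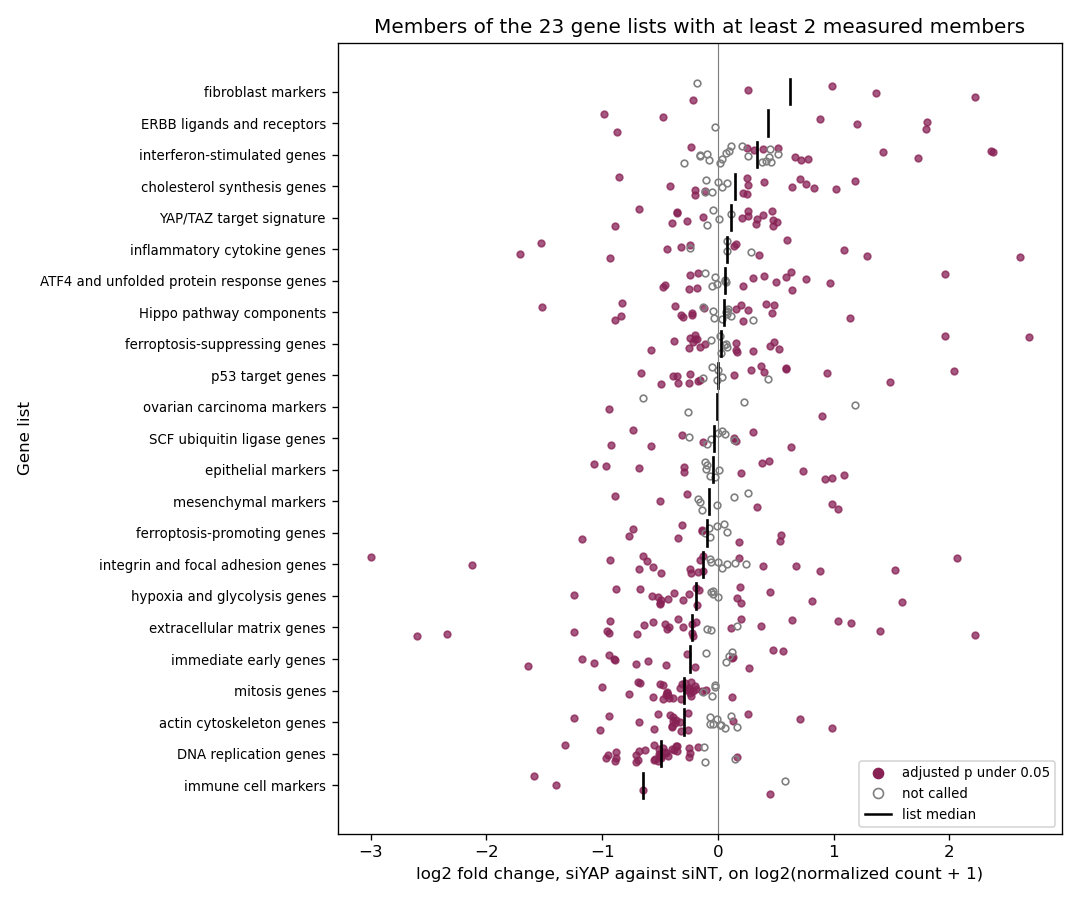
Log2 fold changes (siYAP against siNT, on log2(normalized count + 1)) of the members of 23 gene lists, one point per gene, filled where the limma adjusted p is under 0.05, with a line at each list's median. The medians of the DNA replication, mitosis, actin cytoskeleton and hypoxia and glycolysis lists lie at -0.49, -0.29, -0.29 and -0.19.

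The lists were compared with all other tested genes by camera with a preset inter-gene correlation of 0.01, adjusted over the 23 lists with at least 2 measured members. The 4 lists that passed all lost the call with an estimated correlation, as given beside each. For the Hippo, p53, inflammatory, epithelial, mesenchymal and ovarian lists the median, the mean and the camera direction did not all have the same sign. The medians of the p53 and ovarian lists changed sign with upper-quartile factors, that of the p53 list also with TMM factors, and those of the SCF, p53, epithelial, mesenchymal and ovarian lists with equal totals.

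The 3 heptamers named above came from a search of a single annotated 3′ UTR per gene, made after the gene changes had been seen. Among 11396 genes with a mean of at least 50 normalized counts, those with TTCTTAA in the 3′ UTR (2572 genes) had fold changes that were lower than those of other genes of like UTR length, base content and expression (coefficient -0.174 on the log2 scale, standard error 0.013). The coefficients were -0.099 for GAGAGGA (1811 genes) and -0.118 for GATAAAG (1120 genes). At least 1 of the 3 was present in 106 of 186 searched genes that fell at least 2-fold (57.0%) and in 4118 of the 11210 other genes (36.7%). The heptamers were chosen on these same fold changes and the shares are not corrected for UTR length, so they describe the genes and test nothing. ACTG1, VIM, NDRG1, PTGS2, TGFBI, KIF2C and CCNF each hold 1 and MYLK holds 2. Named genes that rose hold them too: COL4A4 holds 2 and SLC7A11, ITGA1, LUM and RIGI hold 1 each. Among named genes that were called, 18 of 45 lower and 6 of 27 higher hold at least 1.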

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

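The edgeR, DESeq2, equal-total, TMM, camera-without-trend and heptamer-free alternatives were chosen after seeing the data. Under all alternatives run, YAP1 stayed called, with log2 fold changes of -4.27 to -4.38 when 1 library was left out. Called genes numbered 8756 to 9818 with 1 library left out (4376 to 4942 higher, 4380 to 4876 lower). Among genes without the 3 heptamers, 5480 were called of 8511 tested (2885 higher, 2595 lower), and 602 rose and 167 fell at least 2-fold; fewer genes were tested. Requiring a 2-fold change left 1525 genes (1086 higher, 439 lower).

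With an estimated correlation, the list tests gave adjusted p = 0.0681 for DNA replication, 0.636 for mitosis, 0.665 for the actin cytoskeleton and 0.665 for hypoxia and glycolysis. Among genes without the heptamers, the DNA replication (4.83e-10, median -0.51) and mitosis lists (1.01e-06, median -0.25) still passed, and the actin (median -0.07) and the hypoxia and glycolysis lists (median -0.19) each gave 0.142, with fewer members. With 1 library left out, the hypoxia and glycolysis test ranged from 0.0107 to 0.0529, above 0.05 in 1 case, without siNT replicate 2; the cause was not tested. The 72 named genes other than YAP1 kept their call in all 1197 comparisons and their direction in 1193. The 4 others were CYBB, never called: -0.66 to 0.49 with 1 library left out (above 0 without siNT replicate 1 or siYAP replicate 1), 0.0067 with equal totals and 0.22 with DESeq2. Of 399 comparisons for the 19 lists that had not passed, 35 now passed, all with fry, which asks whether the members change and not whether they differ from other genes. In 17 the direction turned with no call on either side. With fry the adjusted p was then 0.994 (YAP/TAZ), 0.0613 (epithelial) and 0.358 (ovarian). Without the heptamers it was 0.637 (Hippo), 0.936 (ferroptosis-suppressing) and 0.936 (p53), and without the camera trend 0.953 (inflammatory) and 0.932 (epithelial). The epithelial list gave 0.995 with the replicate block and 0.768 to 0.980 over the 6 fits with 1 library left out, of which 4 turned, and the ovarian list 1.000 with values of at least 5 and 0.868 to 0.981 over those fits, of which 3 turned. The cause was not tested.

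Libraries of the same number did not deviate together (correlations -0.34, -0.01 and -0.07), and those of different numbers gave -0.27 to 0.32. The values thus show no pairing by number, but 3 libraries per group are too few to exclude it. With a replicate block, 9141 genes were called (4654 higher, 4487 lower) and YAP1 was at -4.32. Genes near the floor, such as CYBB, are limited by depth.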

Other observations

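Genes of secreted plasma proteins made by hepatocytes were examined outside the fixed lists. The list of 50 such genes was written after AGT, VTN and others had been seen among the largest rises, so its count is not independent evidence and no set test is given. Of 33 measured members, 27 rose, 2 fell and 4 were not called, with a median log2 fold change of 2.71. The fibrinogen chain genes FGA and FGB rose by 3.02 and 2.99 on the log2 scale, TTR, the thyroxine carrier, by 4.25, SERPINA1, alpha-1-antitrypsin, by 3.53, and AFP, alpha-fetoprotein, by 2.44. SERPIND1 (log2 -0.91) and LCAT (log2 -0.45) fell. In siNT, 30 of the 33 had a mean of at least 5 normalized counts and 18 of at least 50, and 0 were in the fixed lists. Transcription factors of liver and gut epithelium were expressed in both groups: HNF4A rose by a log2 of 0.93 and FOXA1 by 0.71, while FOXA2 fell (log2 -0.52). The epithelial brush border gene VIL1 rose by 2.09. These genes were chosen after their values were seen.

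A set of 19 gene families, grouped by symbol after the data had been seen, gave further groups; none passed with an estimated correlation (adjusted p of 0.0962 to 0.909). Genes of cytosolic ribosomal proteins were lower in 59 of 77 cases and higher in 3 (median -0.25), those of mitochondrial ribosomal proteins lower in 48 of 75 (median -0.18) and those of the proteasome lower in 25 of 36 (median -0.23). The 6 CCT chaperonin genes matched by symbol were lower, as were 8 of 12 keratins, with none higher; of CCT genes outside the match, TCP1 (log2 -0.35) and CCT6A (log2 -0.12) were lower and CCT6B was higher (log2 1.05). Aldehyde dehydrogenase genes were higher in 12 of 14 cases and all 6 UDP-glucuronosyltransferase genes were higher (UGT2 genes, median 2.38), which as close paralogs can share reads. With equal totals these medians kept their sign, and 50 of 77 and 31 of 75 ribosomal protein genes were lower; the medians of claudins and matrix metalloproteinases changed sign. The pseudogene NCAPD2P1 rose from 157 ± 8.10 to 2265 ± 78.5 normalized counts (SD, n = 3) while its parent NCAPD2 fell (log2 -0.32), and reads may be assigned to either, a question left untested by the alternatives, in which edgeR called 9571 genes in all.

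In the weighing that follows, the scaling tests, the hepatocyte RNA test, the coding-sequence test and the test of all 6 heptamers of genes that rose were chosen after the values had been seen. The split of the libraries into siNT and siYAP called 9767 genes, and the highest of the 9 other splits called 0 (limma), so 1 of 10 splits gave as many. Every other split mixes siNT and siYAP libraries on both sides. That turns the group difference into spread, so few calls there were to be foreseen. In addition, 10 splits are too few for a share under 0.05.

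Over 11396 genes, 3 leading heptamers in 3′ UTRs went with lower fold changes, with regression statistics of -13.4, -7.24 and -7.14. The link was weak per gene: uncorrected median log2 fold changes were -0.023, -0.04 and -0.048 with 1, 2 and 3 of them. Falls of at least 2-fold were seen in 2.24%, 3.34% and 2.86% of these genes, against 1.12% with none. Rises of at least 2-fold were seen in 4.36%, 3.34% and 5.14%, against 4.39% with none. Base content alone is argued against, since the lowest statistic among 213 shuffled heptamers of the same bases was -2.78, and chance over genes is too, since the lowest in 100 shuffles of the fold changes was -4.80. A candidate explanation is that the siRNAs against YAP1 silence other transcripts through their seeds. For a siRNA strand that pairs with YAP1 throughout its seed, this would put each heptamer in the YAP1 mRNA. Seeds of the other strand were not searched for. All 3 heptamers were found in the YAP1 mRNA. So were 3 of the 6 leading heptamers of the genes that rose (ATTACAA and CACACAC in the 3′ UTR, ACAAATG in the coding sequence), so presence alone tells little. The bound set beforehand for this test was missed: 182 of 2643 other mRNAs of like length (6.89%) also hold all 3, over the 5% set, so whole mRNAs leave it open; sharing by other long mRNAs lowers what the test can tell but is not something the explanation forbids. In coding sequences, where all 3 lie in YAP1, 6 of 3397 of like length (0.177%) hold them, but this test was added once the other had missed its bound and the heptamers were known to lie there, so it decides nothing; the siRNA sequences were not analysed here, and a microRNA or an effect of YAP1 loss on such genes stays open and untested.

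The rise of hepatocyte plasma protein genes may be a response of these cells or a technical effect. RNA of hepatocytes is argued against by 4 abundant transcripts (ALB, APOA2, APOB and APOC3, picked after the values had been seen), of which ALB gained most, 57.4 normalized counts or 2.46% of the gain of FGB, although SERPINA1 (13.9%), APOH (18.5%) and APOE (27.9%) gained more and a source that makes little ALB is not excluded. A change of scaling moves all genes alike. Over the scalings, the median of all tested genes was 0.004 to 0.09 and that of the list 2.71 to 2.8, a gap that argues against scaling. Seed matches of the non-targeting siRNA, whose sequence was not analysed here, stay open: the median was 2.71 in the 31 of 33 members without ATTACAA, the heptamer that led among genes that rose (statistic 7.79, against a highest of 4.95 in 100 shuffles), and 2.39 in the 27 with none of the 6 leading ones, but too few members hold them for leaving these out to decide. Loss of YAP1 remains as a hypothesis, and seed effects of the siRNAs against YAP1 or of the non-targeting siRNA on a regulator of these genes were not tested and are confounded with the group. MicroRNAs that act through the heptamers of genes that rose were not tested either.

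CCN2 and ANKRD1 rose although YAP1 was at 5.00% of control and both are standard readouts of YAP activity. Over the scalings, the log2 fold changes of the 2 genes ran from 0.48 to 0.57. Each alternative scaling raised the median of all tested genes, from 0.004 to between 0.005 and 0.09. None of them could therefore lower the rise. Both genes lay above that median under each scaling, at 0.48 against 0.004 with the authors' size factors and 0.57 against 0.09 with equal totals. That gap argues against scaling for their rise relative to the median gene, while a shift of all genes alike stays open. Seed matches of the non-targeting siRNA, which would release these genes in siYAP, stay open. Of 2 searched 3′ UTRs, 0 hold ATTACAA, but 77.6% of gene pairs would lack it by chance at its share of 11.9% of 3′ UTRs. The 3′ UTR of CCN2 holds 2 of the 6 leading heptamers of genes that rose (TTTGCAC and ACAAATG), and that of ANKRD1 holds none. At least 1 of the 6 is in 43.0% of searched 3′ UTRs. The statistics of TTTGCAC and ACAAATG (4.87 and 4.86) lie under the highest of 4.95 in shuffles, so these sites decide nothing. Whether a microRNA acts through them was not tested. A biological cause, such as input from other regulators while WWTR1 stayed at 56.4% of control, may account for the rise and was not tested.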
